A study of Gallus gallus with 2 samples.

How the data were processed

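Gene expression in intestinal intraepithelial lymphocytes, the T cell rich population that lies between the epithelial cells of the gut lining, was compared between broiler chickens fed a diet with direct fed microbials (DFM, live bacteria given in feed) and untreated control chickens at day 14. Total RNA of both groups was hybridised together on each of 2 two-colour Agilent chicken arrays on 1 slide. On the array of replicate 1 the DFM RNA carried Cy5 and the control RNA Cy3, and on the array of replicate 2 the dyes were exchanged. The labels call the second array both a biological replicate and the dye exchange of the first, and they do not say how many birds gave each RNA. The p-values therefore measure only the spread between 2 arrays, which may be technical.

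Per the file headers, the deposited intensity values are the mean brightness of each spot and the median brightness of its local background in both dyes, not yet background-corrected. The deposited files also hold, per the file headers, a log10 ratio of Cy5 over Cy3 after the scanner software's own background subtraction and dye normalization, and a p-value of that ratio from an error model within 1 array. Flags for spots well above background, saturated spots, outliers and control spots are likewise deposited. The authors' series table holds log2 values. Set against the scanner values over 42034 probes, its column for replicate 1 correlated with the log2 ratio of Cy5 over Cy3 at r = 1 and its column for replicate 2 at r = -1, so both columns give DFM over control with no further centring. Their medians were -0.274 and 0.204, and neither scale, centring nor direction stayed unknown. The submitters' processing notes name Agilent Feature Extraction 10.7.3.1, whereas the file headers record version 9.5.3.1, and the array grid was built on galGal2 per the file headers.

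Each array held 43451 spots, of which 1417 were controls and 42034 were probes. Mean signals were background-corrected with the normexp method at an offset of 50 and normalized within each array by loess, with control spots at weight 0, in limma 3.58.1 under R 4.3.3 with the data.table package (1.17.8). Control spots and the 5 probes with an outlier flag on replicate 2 (0 on replicate 1) were left out, and no probe was saturated on either array. On replicate 1, 16889 probes were well above background in Cy3 and 21122 in Cy5, against 17331 and 20465 on replicate 2. Probes entered the test if they were well above background on both arrays in the channel of at least 1 group, which left 18242 probes and dropped 23788. The number of arrays limits the precision of all values. The offset and the array's signal range compress ratios: in simulated data on 18242 probes for the comparison of DFM with control, a 2-fold change was measured at a median log2 value of 0.79.

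The ratio of the second array was turned so that all values are log2 of DFM over control. Each probe was tested against 0 with limma's lmFit and eBayes (1 residual degree of freedom, 7.52 prior degrees of freedom, prior variance 0.0349), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A dye term would have left no residual degrees of freedom. SE is limma's moderated standard error, and n is 2 arrays. On simulated data with 50 changed probes of each size among 18242, the test recovered 14% of probes changed 1.5-fold, 72% of those changed 2-fold, 98% of those changed 3-fold and 100% of those changed 4-fold, and called 5 of 18042 unchanged probes. The simulated noise was drawn from the prior variance fitted to these 2 arrays, so these rates do not cover the spread between birds.

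Probes were named from the accession, gene identifier or symbol in the files through an NCBI RefSeq table of assembly GRCg7b, used only for names. Of 42034 probes, 10091 were named, 5269 by accession, 2353 by gene identifier, 2059 by symbol and 410 by synonym, and 31943 stayed unnamed here. Of the tested probes, 6483 carried a gene symbol. A gene with several tested probes was represented by the brightest, giving 5865 genes, tested in a fit of their own. Among the 548 genes with more than 1 tested probe, all tested probes were called in 1 direction in 30, called and uncalled probes occurred together in 134, and 6 genes (BEND7, DYNC1H1, EPHX2, MUC2, TBC1D14 and TRIM2) had probes called in opposite directions. A probe that was well above background on no array of a group has only a bound there, and where 1 of the 2 arrays was dim the measured fold is given and the dim array stated. Its fold change is given as at least the mean of the bright group over the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own, on normalized log2 values after loess and Aquantile.

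The lists and the rule for named genes were fixed before the data were examined. The 22 lists cover T cells and TCR signalling, cytotoxic and NK cells, B and plasma cells, macrophages and granulocytes, erythrocytes and thrombocytes, enterocytes, epithelial junction and mucus, stroma and smooth muscle, exocrine pancreas, interferon response and antigen presentation, cytokines and chemokines, TLR and NF-kB signalling, antimicrobial peptides, cell cycle, ER stress and heat shock, immediate early genes, cholesterol and fatty acid synthesis, antioxidant and xenobiotic genes, apoptosis, glycolysis, cytosolic ribosomal proteins and mitochondrial oxidative phosphorylation. The naming table matched some entries to another symbol, which may name a different gene. Among them were BLNK to SH2D6, KRT19 to KRT24, KRT20 to KRT40, MUC6 to OVOB, CCNB2 to CCNB1, KIF4A to KIF4B, ALAS2 to ALAS1, PKM to PKLR, PGK1 to PGK2, SLC2A3 to SLC2A14, IRF3 to IRF7, XIAP to BIRC8, GSTO1 to GSTO2, PNLIP to PNLIPRP1 and S100A9 to S100A12. These matches were not checked and count in their lists. Lists with at least 5 tested genes were compared with all other genes by limma's camera with a preset inter-gene correlation of 0.01, adjusted over 21 lists. On simulated data of 5865 genes, a list of 20 genes shifted by 0.5 log2 was called in 40 of 40 draws with the preset correlation and in 0 of 40 with an estimated correlation, and 2 of 800 unshifted lists were called. The simulated genes varied independently of each other, so these draws do not show how the preset correlation performs on genes that vary together. In these draws an estimated correlation from 2 arrays called nothing at that size.

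The named genes are the 12 highest and 12 lowest genes with a symbol, ranked by the smaller of the absolute log2 ratios of the arrays, with the same direction on both and an adjusted p under 0.05; up to 4 members of each list with the largest such value; and, where measured, IFNG, IL2, IL6, IL8, IL10, IL15, IL17A, IL18, TGFB3, TNFSF15, LITAF, NOS2, CD3E, CD4, CD8A and MUC2. Some genes that meet the rule are not reported here. Other list members are named where a list is described and were chosen after their values were seen. Alternatives tried were other background corrections, the scanner software's own ratio, the authors' series table, median centring, Aquantile, other filters on dim probes, outlier flags kept, other empirical Bayes settings or none, other fold thresholds, other probe summaries and list tests, each replicate left out, and the arrays averaged as 1 technical dye swap. Scaling to the spike-in RNAs and a count over probes with a gene symbol were added after seeing the data.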

Results

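The series asked how feeding direct fed microbials (DFM) affects gene expression in the intestinal intraepithelial lymphocytes of broiler chickens at day 14. RNA of DFM-fed chickens was compared directly with RNA of untreated chickens on 2 dye-swapped arrays. In all 4 channels together, 15792 of 42034 probes were well above background, and 18242 probes were tested. The p-values measure only the spread between these 2 arrays, which may be technical.

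Feeding DFM was accompanied by a much higher signal of digestive enzyme genes of the exocrine pancreas, led by the carboxypeptidase gene CPA1 at 45.8-fold, and by higher signals of the chemokine gene CCL20, the inducible nitric oxide synthase gene NOS2 and the chemokine gene CCL4. The heat shock chaperone gene HSPA2 was 8.83-fold lower, the cytotoxic protease gene GZMA 3.14-fold lower, and lists of enterocyte, epithelial junction, glycolysis, immediate early and cytotoxic genes were lower than other genes with the preset correlation. None of these lists was called with an estimated correlation (adjusted p = 0.625 for each). In simulated draws that test called a list shifted by 0.5 log2 in 0 of 40, so it cannot decide for or against these calls. The T cell list was not called. The directions of single genes are relative to the average probe of each array, which loess sets to 0, and those of lists are relative to other genes. Set to the spike-in RNAs instead, a scaling chosen after seeing the data, 18223 of 18242 probes were called higher and 3 lower. That scaling took the same shift for both arrays, so these calls leave out the spread of the spike-in RNAs between arrays.

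Of the 18242 tested probes, 4120 passed limma's test at an adjusted p under 0.05, 2202 of them higher and 1918 lower with DFM, so that 53.4% were higher. With median centring in place of loess the split was 109 higher and 8 lower. At gene level, 561 of 5865 genes were higher, 970 were lower, and the median log2 ratio was -0.08. At least 2-fold on both arrays and in the same direction were 324 higher and 117 lower probes, against 14.2 and 2.71 if the arrays were independent, and 1 probe was 2-fold in opposite directions, against 12.5. These counts were 1033 higher and 677 lower with the scanner software's ratio, and 207 and 39 with median centring, where 204 were opposite. Across the tested probes, which are not independent replicates, the ratios of the arrays correlated at Pearson r = 0.82 and Spearman rho = 0.72. The scanner software's Cy5 over Cy3 ratios correlated at r = -0.77 between arrays, the sign the labelled dye exchange gives. By the software's own within-array p at 0.01 on both arrays, 1865 probes were higher, 1860 lower and 45 opposite.

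**Figure D1:**
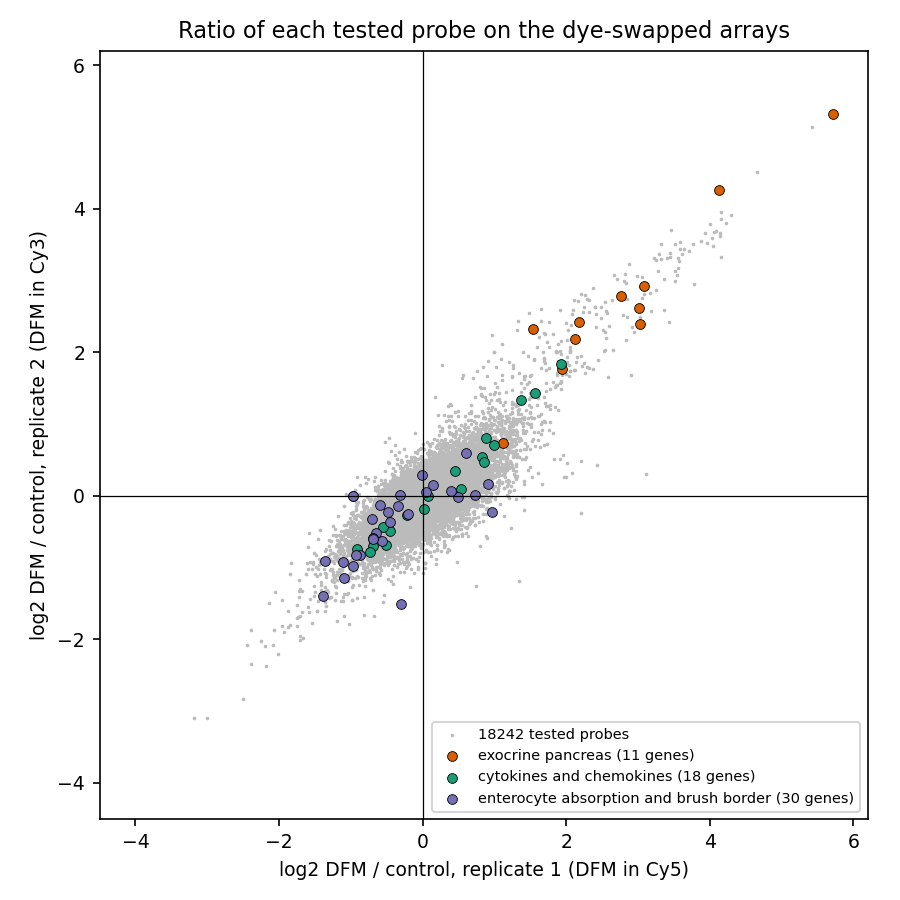
Log2 ratio of DFM over control for each of 18242 tested probes on replicate 1 (horizontal axis) and replicate 2 (vertical axis), relative to the average probe of each array, with genes of 3 lists coloured. All 11 exocrine pancreas genes lie above 0 on both arrays, with a median of 2.70, and 20 of 30 enterocyte genes lie below 0 on both; scaled to the spike-in RNAs, most probes would lie above 0.

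The highest genes outside the pancreatic enzymes have varied functions. PDPR, a regulatory subunit of pyruvate dehydrogenase phosphatase, had log2 ratios of 4.14 and 3.67 on the arrays (mean 3.90, SE 0.15, n = 2 arrays, adjusted p = 6.68e-09), while its second probe measured 0.80 and 0.36. The endocytic adaptor gene SH3BP4 was 12.5-fold higher, the acetylcholinesterase gene ACHE 11.8-fold and the sulfate donor synthase gene PAPSS1 10.4-fold, and the ephrin gene EFNA2 had a mean log2 ratio of 3.42. WNT4, a secreted signalling protein gene, was 9.64-fold higher, the Wnt coactivator gene BCL9L 9.17-fold and the translation initiation scaffold gene EIF4G1 8.21-fold. The opsin-like gene RGR was 9.99-fold higher, with control signal well above background on 1 of the 2 arrays. A second probe of SH3BP4 and of EFNA2 was not well above background.

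The lowest gene was HSPA2, with log2 ratios of -3.18 and -3.10 (mean -3.14, SE 0.13, n = 2 arrays, adjusted p = 1.16e-08), and its second probe measured -3.01 and -3.10. The matrix Gla protein gene MGP, an inhibitor of calcification, was 6.36-fold lower by its bright probe, while a dim second probe measured -0.23 and -0.29. PDK4, a kinase that inhibits pyruvate dehydrogenase, was 5.17-fold lower. The transcription factor gene KLF6 was 4.33-fold lower, the receptor gene GPRC5A 4.23-fold and PMM2, a phosphomannomutase gene, 4.38-fold. OC3 was 4.39-fold lower, with DFM signal well above background on 1 of the 2 arrays. SERPINF1, which encodes pigment epithelium-derived factor, fell by 1.98 on the log2 scale, the cytochrome P450 gene CYP2C23b by 1.83, and RGS1, a regulator of G protein signalling in lymphocytes, by 1.83. For CDHR2, a protocadherin gene of the enterocyte brush border, the log2 ratio was -1.72, and for the tetranectin gene CLEC3B it was -1.69.

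Exocrine pancreas genes rose together: 11 of 11 tested members were higher, 0 lower and 0 not called, and all 11 were higher adjusted over the list alone. Their median log2 ratio was 2.70, or 6.52-fold, and the list was called at an adjusted p = 1.93e-21 by camera with the preset correlation (adjusted p = 0.625 with an estimated correlation). CPA1 reached log2 ratios of 5.72 and 5.32, and the elastase gene CELA2A 4.13 and 4.26. PNLIPRP1, which encodes a pancreatic lipase-related protein, was at least 6.45-fold higher, since its control signal was not well above background on either array (adjusted p = 2.56e-08). The pancreatic amylase gene AMY2A had a mean log2 ratio of 2.31, the bile salt-activated lipase gene CEL 2.15 and the chymotrypsin-like gene CTRL, the smallest change of the list, 0.93. Only 6 of the 11 members were well above background in both channels on both arrays. The others, PNLIPRP1 among them, had a dim channel on at least 1 array, so the median rests partly on dim signal. With PNLIPRP1 and any other member lacking control signal above background at its bound, the median was 2.69. The trypsinogen genes PRSS2 and PRSS3 were not well above background in any channel.

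Cytokine and chemokine genes moved both ways, and the list's median was 0.26 on replicate 1 and 0.05 on replicate 2. Of 18 tested, 8 were higher, 6 lower and 4 not called, with the same 8 and 6 adjusted over the list alone, and the list was not called (median 0.18, adjusted p = 0.114; adjusted p = 0.813 with an estimated correlation). CCL20, which attracts CCR6-bearing lymphocytes and dendritic cells, was 3.68-fold higher (log2 ratios 1.92 and 1.84), NOS2 2.83-fold and CCL4 2.56-fold. The homeostatic chemokine gene CCL19 was 1.81-fold higher and the granulocyte growth factor gene CSF3 1.80-fold. TNFSF15 was 1.61-fold higher and IL17A, the signature cytokine gene of Th17 cells, 1.58-fold. For CSF3 and IL17A the control signal was well above background on 1 of 2 arrays. The chicken interleukin 8 gene IL8L2 was at least 1.30-fold higher, with no control array well above background (adjusted p = 0.0392). Lower were IL16, IL15 (log2 ratios -0.73 and -0.78, a growth factor of intraepithelial lymphocytes), the cyclooxygenase gene PTGS2, the lymphotactin gene XCL1, LITAF and CCL1. The second, dim probe of LITAF measured 0.15 and -0.01. TGFB3 measured 0.54 and 0.10 and was not called. IFNG, IL2, IL6 and IL10 were not well above background in any channel, and IL18 in only 1 control channel.

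Lymphocyte and other blood cell markers showed a lower cytotoxic list and mixed or small changes elsewhere. Of 7 cytotoxic and NK genes, 0 were higher, 3 lower and 4 not called (5 lower adjusted over the list alone), with a median of -0.37 (-0.51 and -0.22 on the arrays) and an adjusted p = 0.0394 (adjusted p = 0.625 with an estimated correlation). This call was also lost with offset 0 (adjusted p = 0.0691), with median centring (0.0501), with the scanner software's ratio (0.103) and with shared genes left out (0.0861). GZMA had log2 ratios of -1.68 and -1.62, XCL1 of -0.51 and -0.69, and the NK receptor gene CD244 of -0.64 and -0.45, while FASLG measured -0.45 and -0.22 and was not called. Of 18 T cell genes, 3 were higher, among them CD5 and CD40LG at 0.61 and 0.59, 3 were lower (IL2RG, CD3D and CD3E) and 12 were not called, with the same counts adjusted over the list alone. CD3E measured -0.79 and -0.14 (adjusted p = 0.0491), CD8A -0.16 and -0.09, and CD4 0.27 and 0.38 with control signal well above background on 1 array. Neither CD4 nor CD8A was called. Both were dim, with a mean log2 signal of 6.35 for CD4 and 6.39 for CD8A, against 5.92 for IFNG, which was not detected. The offset compresses ratios at such levels, so the missing calls say little. The T cell list's median was -0.10 and its mean -0.04, while the test placed it on the higher side of other genes (adjusted p = 0.831; adjusted p = 0.860 with an estimated correlation).

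Of 12 B and plasma cell genes, 1 was higher, 2 lower and 9 not called, or 1 and 3 adjusted over the list alone (median -0.14, adjusted p = 0.597). The polymeric immunoglobulin receptor gene PIGR, which epithelial cells use to export IgA, was 2.27-fold higher, and the B cell kinase gene BTK 1.71-fold lower, while BLK measured -0.25 and -0.40 and was not called. Of 19 macrophage and granulocyte genes, 3 were higher, 2 lower and 14 not called, with the same counts adjusted over the list alone (median 0.09, adjusted p = 0.191). The myeloid calcium-binding protein gene S100A12 was 2.54-fold higher, the lysozyme gene LYZ and CEBPB were 1.68-fold and 1.67-fold higher, and the goose-type lysozyme gene LYG2 was 1.91-fold lower. Of 10 erythrocyte and thrombocyte genes, 1 was higher, 4 lower and 5 not called, or 1 and 5 adjusted over the list alone (median -0.30, adjusted p = 0.191). HBE1 was 3.70-fold higher with control signal well above background on 1 array, and the globin gene HBBA, the carbonic anhydrase gene CA2 and FAXDC2 were 1.71-fold, 2.19-fold and 1.57-fold lower.

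Genes of the absorbing epithelium were lower as lists. Of 30 enterocyte genes, 2 were higher, 14 lower and 14 not called, or 2 and 18 adjusted over the list alone, with a median of -0.45 (-0.52 and -0.24 on the arrays, adjusted p = 0.0188; adjusted p = 0.625 with an estimated correlation). The calcium-binding protein gene CALB1 was 2.63-fold lower (log2 ratios -1.39 and -1.40), the transcription factor gene HNF4A 2.18-fold, the amino acid transporter gene SLC7A9 2.03-fold and the apolipoprotein gene APOB 1.97-fold. The fatty acid-binding protein genes FABP6 and FABP1 were higher, FABP6 at 0.61 and 0.59 on the arrays and FABP1 unevenly at 0.91 and 0.16. Of 22 epithelial junction and mucus genes, 2 were higher, 12 lower and 8 not called, also when adjusted over the list alone, with a median of -0.44 (adjusted p = 0.0347; adjusted p = 0.625 with an estimated correlation). This call was also lost with offset 0 (adjusted p = 0.127), with median centring (0.0501) and with the scanner software's ratio (0.200). The desmosome gene DSP was 2.31-fold lower, the endocrine cell marker CHGA 1.79-fold and the junction gene OCLN fell by 0.69 on the log2 scale. The probes of the mucin gene MUC2 disagreed: its bright probe measured -1.15 and -0.69 and its dimmer probe 1.23 and 0.39, both called.

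Stress-response and energy genes included some of the largest decreases. Of 16 immediate early genes, 1 was higher, 5 lower and 10 not called, with the same counts adjusted over the list alone (median -0.22, adjusted p = 0.0394; adjusted p = 0.625 with an estimated correlation). Besides KLF6 and RGS1, the quiescence-associated factor gene KLF2 was 2.00-fold lower and the phosphatase gene DUSP1 1.55-fold lower, whereas JUN was higher at 0.43. Of 20 glycolysis genes, 1 was higher, 9 lower and 10 not called, or 2 and 10 adjusted over the list alone (median -0.33, adjusted p = 0.0188; adjusted p = 0.625 with an estimated correlation). PGAM1 was 2.23-fold lower, GAPDH 2.12-fold and LDHA 1.62-fold. PDK4, the lowest member of this list, restrains pyruvate oxidation rather than acting in glycolysis itself. Of 36 ER stress and heat shock genes, 3 were higher, 8 lower and 25 not called, or 4 and 10 adjusted over the list alone (median -0.17, adjusted p = 0.343). Besides HSPA2, the lower genes included its co-chaperone gene BAG3, 3.15-fold lower, HSPA4L, 1.79-fold lower, and ATF4, 1.45-fold lower.

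The remaining lists were not called. Of 18 cholesterol and fatty acid synthesis genes, 1 was higher (MVD, 0.82), 7 were lower, led by FDFT1 (2.06-fold), MSMO1 (1.99-fold) and ME1 (1.63-fold), and 10 were not called, or 1 and 8 adjusted over the list alone (median -0.28, adjusted p = 0.142). Of 44 antioxidant and xenobiotic genes, 6 were higher, 17 lower and 21 not called, or 7 and 18 adjusted over the list alone (median -0.20, adjusted p = 0.237), with CYP3A4 at -1.47, ALDH3A2 at -1.11, PRDX6 at -0.92 and GSTT1 at 1.03. The median of this list was -0.38 on replicate 1 and -0.13 on replicate 2. Of 24 interferon and antigen presentation genes, 3 were higher, 7 lower and 14 not called, or 4 and 8 adjusted over the list alone (median -0.20, adjusted p = 0.543), with IFIT5 at -0.90, ZNFX1 at -0.82 and B2M at -0.51. Of 30 apoptosis genes, 2 were higher, 8 lower and 20 not called, also when adjusted over the list alone (median -0.15, adjusted p = 0.230), with PDCD10 at -0.93, BNIP3L at -0.77 and FAS at -0.67. Of 20 TLR and NF-kB genes, 2 were higher (NFKBIZ, 0.88, and TIRAP, 0.72), 4 lower, led by BIRC2 (-0.90) and MYD88 (-0.62), and 14 not called, or 3 and 8 adjusted over the list alone (median -0.17, adjusted p = 0.751). The median of the TLR and NF-kB list was -0.23 on replicate 1 and -0.01 on replicate 2. Of 35 cell cycle genes, 1 was higher, 3 lower and 31 not called, also when adjusted over the list alone (median -0.16, adjusted p = 0.363): E2F1 was 2.79-fold higher, and SMC2 was 1.35-fold lower.

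Of 12 stroma and smooth muscle genes, 2 were higher, 4 lower and 6 not called, or 2 and 6 adjusted over the list alone (median -0.30, adjusted p = 0.464). POSTN, a matrix protein gene, was 2.21-fold lower, and MYH11, measured with DFM on 1 of 2 arrays, was 1.70-fold lower. PECAM1 was 1.84-fold higher by its brightest probe, while its other probes were not called. The probe of FBN1 that was well above background in control on 1 array was 7.30-fold higher, while a second tested probe measured -0.23 and -0.12. Of 35 ribosomal protein genes, 4 were higher, 4 lower and 27 not called, or 4 and 3 adjusted over the list alone (median 0.05, adjusted p = 0.191), among them RPL22 (0.53), RPL3 (0.49), RPL7L1 (-0.55) and RPL6 (-0.40). Of 32 oxidative phosphorylation genes, 0 were higher, 6 lower and 26 not called, also when adjusted over the list alone. Their median differed in sign between the arrays, at 0.08 on replicate 1 and -0.06 on replicate 2. The median of that list was 0.05 and its mean -0.05, while the test placed it on the higher side of other genes (adjusted p = 0.751); UQCRC1 and NDUFA9 fell by 0.87 and 0.71 on the log2 scale, NDUFV3 by 0.59 and UQCRFS1 by 0.46. Only 4 antimicrobial peptide genes were tested, too few for a list test: LYZ and LEAP2 were higher (0.75 and 0.56), LYG2 was lower (-0.94) and RSFR measured -0.02 and -0.23, with the same calls adjusted over the list alone.

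**Figure D2:**
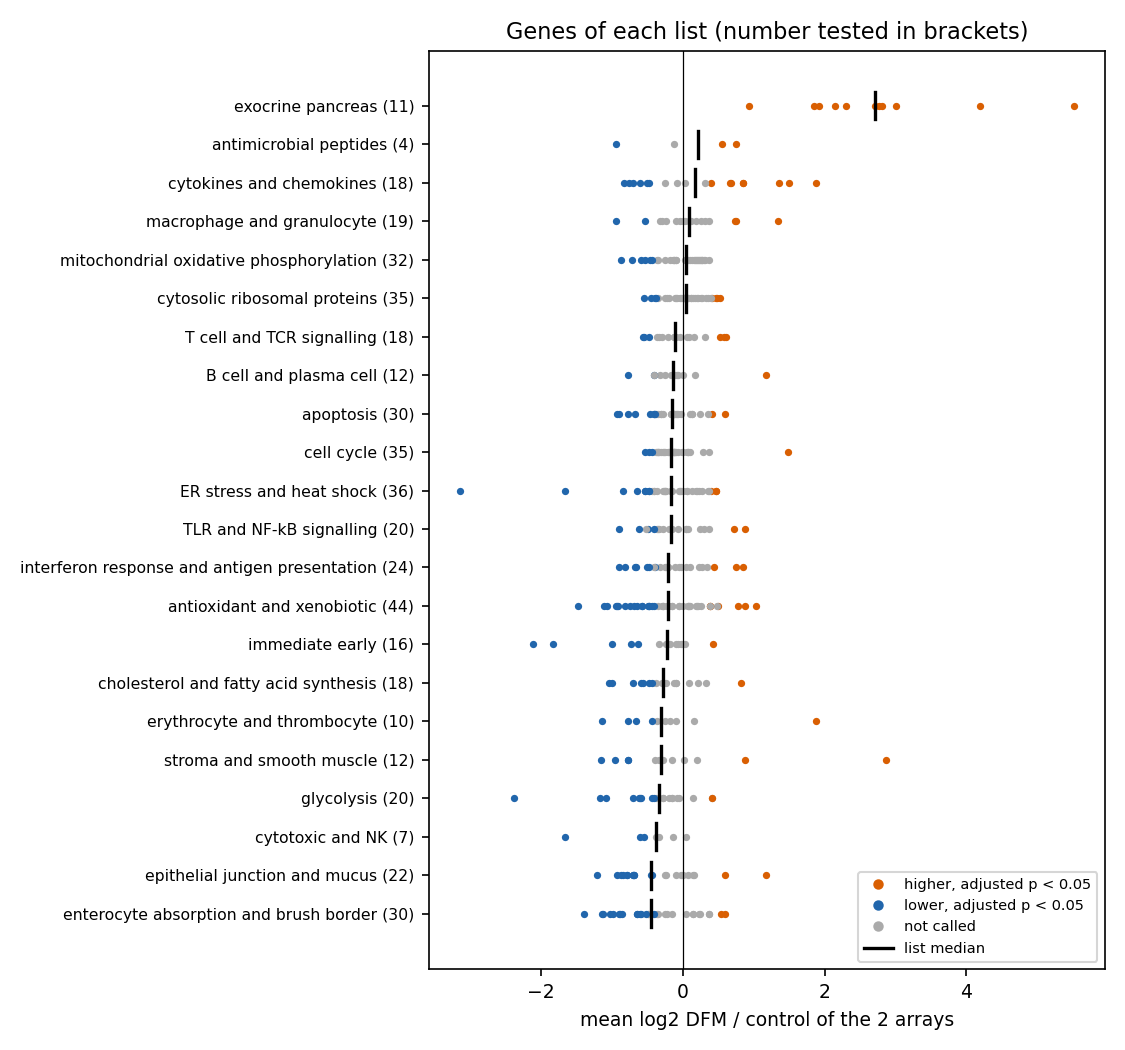
Mean log2 ratio of DFM over control of the 2 arrays for each tested gene of 22 lists, relative to the average probe, coloured by limma's call, with a black bar at each list's median. The exocrine pancreas median is 2.70, and the medians of the enterocyte and epithelial junction lists are -0.45 and -0.44; scaled to the spike-in RNAs all medians would lie above 0.

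**Figure D3:**
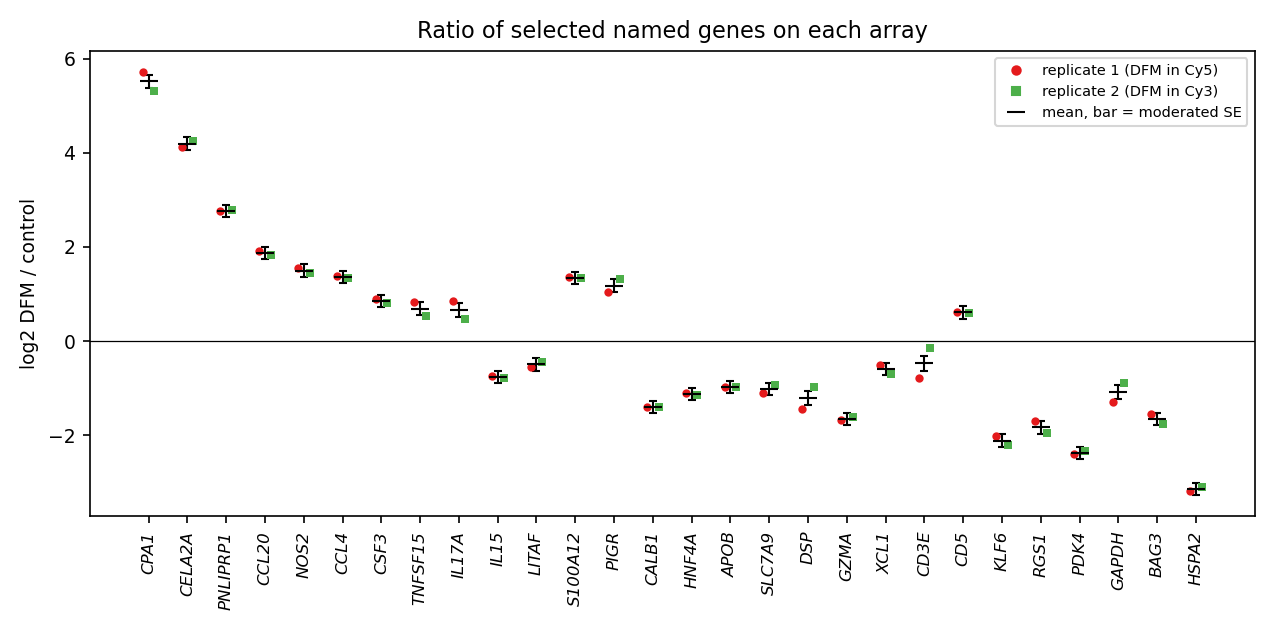
Log2 ratio of DFM over control of selected named genes on replicate 1 (red circles) and replicate 2 (green squares), relative to the average probe, with the mean and limma's moderated SE in black. CPA1 measured 5.72 and 5.32 and HSPA2 -3.18 and -3.10, while CD3E differed between arrays at -0.79 and -0.14; scaled to the spike-in RNAs most genes drawn below 0 would lie above it.

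In all, 6 of 21 tested lists were called with the preset correlation, 1 higher and 5 lower, and 0 with an estimated correlation, where the lowest unadjusted p was 0.0614 for the exocrine pancreas list. With the scanner software's own ratio in place of normexp and loess, 1 list, exocrine pancreas, was called.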

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

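All tests weighed here were chosen only after the result was seen.

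The spike-in RNAs, foreign RNA added to each sample before labelling and used only in the alternative scaling, gave a signal that differed between the groups. Over 10 spike-in RNAs and both arrays, their mean log2 ratio of DFM over control was -2.12 (SD 0.14 between RNAs, range -2.32 to -1.88), or 4.36-fold lower with DFM relative to the chicken RNA. On single arrays the RNAs ranged from -5.56 to 1.15. The RNA at 1.15 on replicate 1 was at -5.56 on replicate 2, and another was at -4.70 and 0.82. For each, the same dye was brighter on both arrays, so the values above 0 followed the dye and not the group. Further RNAs also differed between the arrays, as at -0.32 and -3.81 or -3.48 and -1.04, although 1 was close at -2.13 and -2.51. The SD of 0.14 is therefore that of means over both dyes and not of single arrays. The mean over RNAs and arrays by the scanner software's own ratio was -2.19. The amount of each spike-in RNA per sample is not stated in the labels, and no explanation of the difference between the groups was tested. Of the 1918 probes called lower, 9 lay below this mean, while the directions of probes called higher and of lists against other genes do not depend on it.

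The higher signal of exocrine pancreas genes was set against 2 explanations. Probe-specific signal unrelated to the named genes is argued against, because 10 of 11 list genes but only 67 of 5854 other genes were at least 2-fold higher on both arrays (Fisher's exact p = 9.07e-19). Pancreatic tissue, or RNA from it, in the DFM sample cannot be told apart from a response of the sampled cells to DFM, which was not tested, since either could raise these genes together. Of 3 tested islet hormone genes, 33.3% were higher on both arrays: INS had 1 probe well above background with DFM alone and another at background, while GCG measured -0.34 and -0.21 and IAPP -0.60 and -1.07. Both of the latter were also well above background in control, which could hide a small share of pancreas, and the trypsinogen genes PRSS2 and PRSS3 were not well above background in any channel.

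Probes at least 2-fold higher with DFM in genes with another measured probe formed the second pattern. In the 8 genes with another tested probe, 0% of those 10 probes (median -0.17) were also at least 2-fold higher. The leading probe was the one with the largest ratio, which favours others not following, and the offset compresses the ratios of dim probes. This share therefore cannot decide whether the level of the named gene was the only cause. For BEND7 that cause is argued against, since its other probe measured -0.46 and -0.55 and was called lower. Tested other probes of MTIF2, DAAM2, FBN1 and TRRAP also lay below 0 on both arrays but were dim. The other probe of PDPR (0.80 and 0.36) was called higher and that of ZNF318 (0.34 and 0.58) was higher on both arrays, so a smaller rise stays open there. Those of CADM1 were split (0.41 and 0.45, against 0.05 and -0.13). Dye bias left after loess is argued against, because 0.226% of the 442 probes at least 2-fold on both arrays were opposite in direction. This does not cover the dye bias that loess removed: with median centring 204 probes were opposite, against 246 in the same direction. Signal of a transcript other than the named gene may account for such probes. At the 2-fold threshold following was also rare for the lower probes, in 1 of 6, and these groups cannot be told apart with so few probes (Fisher's exact p = 0.375). By median, other tested probes of lower genes went the way of their leading probes (-0.45), while those of higher genes did not (-0.17). This difference in medians was not tested. Genes without a second measured probe, ACHE, PAPSS1 and WNT4 among them, were not covered, and a response to DFM in part of the transcripts stays open as untested.

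The lower enterocyte genes were the third pattern. Fewer epithelial cells in the DFM sample may account for it, but as the only cause this cannot be told apart from a mixed change: 66.7% of the 30 tested genes (20 genes) lay below 0 on both arrays, FABP6 was called higher, as was FABP1 with uneven arrays, and the epithelial gene PIGR was 2.27-fold higher. Without loess, by median centring, the list's adjusted p by camera was 0.0182, and without background correction it was 0.00669. This argues against either step alone as the cause of the call. No setting left out both steps, so a joint part of them stays open. The call was lost with the scanner software's ratio (adjusted p = 0.103), which has its own background subtraction and dye normalization. There the list's median was -0.58 against -0.45 and the median of all genes -0.16 against -0.08. Ratios were wider there, with 1710 probes at least 2-fold on both arrays in the same direction against 441. These medians therefore cannot show whether the decrease was weaker. A response of the epithelium to DFM was not tested.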

How the results depend on the processing

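Spike-in scaling and the count over probes with a gene symbol were chosen only after the result was seen; all other alternatives were planned. The count of 4120 called probes dropped to 2130 with the scanner software's own ratio and to 2130 with the authors' series table (1179 higher and 951 lower in both, 1543 of them shared with the 4120), to 117 with median centring and to 0 with limma's plain variance and no eBayes, where 2283 passed an unadjusted p of 0.05 against 6744 with eBayes. It was 18226 with spike-in scaling (18223 higher, 3 lower) and 1637 over probes with a symbol (602 higher, 1035 lower). The spike-in scaling took the same shift for both arrays and left out its spread between them. The count of 441 probes at least 2-fold on both arrays became 1013 with a normexp offset of 0, 1710 with the software's ratio and with the series table (60.4% higher, against 73.5%), 246 with median centring (204 further probes went in opposite directions), 1478 at 1.5-fold, 202 at 3-fold, 18022 with spike-in scaling and 135 over probes with a symbol (78 higher, 57 lower). Counted on a single array it was between 581 (without replicate 1) and 923 (without replicate 2). The correlation of the arrays was 0.795 with offset 0, 0.794 with the software's ratio and the series table, 0.762 without a filter and 0.362 with median centring, which leaves the dye trend in the ratios. The 6 called lists became 1 (exocrine pancreas) with the software's ratio and with the series table, and 0 with an estimated correlation. Beyond the thresholds and probe sets, the cause was not tested.

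The other alternatives kept these counts within 1.5 times. Of 1434 values of the 111 named genes under 13 alternatives, 1281 stayed on the same side of the threshold or, with no test, kept their direction, 145 lost the call, 89 of them with median centring and 22 with the software's ratio, and 7 gained it. Some of the 1281 could not have come out otherwise. Aquantile and the averaged arrays left the ratios unchanged, and the named genes had the same direction on both arrays. These settings and each single array therefore gave 111 of 111 by construction. Gene by gene, 19 of the 111 kept their status under every alternative. FBN1 reversed to -0.18 with the strict filter, which takes another probe. MUC2 (-0.06) and LITAF (-0.21) lost their calls with the mean of all probes, and CD3E, XCL1 and CD5 with the software's ratio. Of 22 list medians, 10 moved by more than their spread without replicate 1, with 21 keeping their sign, and 2 without replicate 2. The cytotoxic list was also lost with offset 0, median centring and without shared genes, and the epithelial junction list with offset 0 (adjusted p = 0.127) and median centring (0.0501). The cytokine list was called higher with offset 0, median centring and cameraPR, but its median was -0.08 with the strict filter, which called the erythrocyte list lower (adjusted p = 0.0382). With a single array or the arrays averaged as 1 dye swap no test could be made. The main test is itself paired, because both groups share each array and the ratio within it pairs them. Signal over background limits the dim probes: 263 tested probes were well above background with DFM and on no control array, and 130 the other way.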

Other observations

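The comparison by probe class was chosen only after the result was seen. Tested probes with and without a gene symbol differed in direction. Of 11759 probes without a symbol, 1679 were called higher and 1010 lower (14.3% and 8.59%), whereas of 6483 probes with a symbol 523 were higher and 908 lower (8.07% and 14.0%). Among the brightest of 4 equal brightness groups 19.8% of probes without a symbol and 11.1% of those with a symbol were higher, and among the dimmest 5.30% and 2.41%. The median log2 ratio was 0.04 without a symbol (0.07 on replicate 1 and 0.01 on replicate 2) and -0.07 with a symbol (-0.09 and -0.06).

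Of 263 tested probes well above background with DFM on both arrays and with control on neither, 78 were called higher.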
